A study of Glycine max with 4 samples.

How the data were processed

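Messenger RNA of 4 soybean organs (root, stem, leaf and cotyledon) was measured by sequencing, with 1 library per organ. Per the labels, poly(A) RNA was taken from 15 μg of total RNA and amplified by 15 cycles of PCR. The unit of the deposited values is other: each file lists distinct read sequences with their abundance, a whole number of identical reads, and holds no coordinates, gene names or scaled values. The authors collapsed identical reads. Their processing notes name BWA, whose version, role, genome build and annotation are not given in the sources used here. Reads were 76 nt long in root, stem and leaf and 96 nt in cotyledon, and the cotyledon reads were trimmed to 76 nt.

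The planned feature was the annotated gene. No genome or transcript sequence was used here, so reads could not be matched to annotated genes, and the feature became a contig assembled from the pooled reads of the 4 libraries. This departs from the plan. Adapter sequence was masked first, with at most 1 mismatch over 13 nt inside a read or an exact match of at least 6 nt at its end. A greedy assembler written in C++ (g++ 11.4.0) used 25-mers found in at least 2 distinct reads, dropped a 25-mer when an alternative differing in its first or last base was 20 times as abundant, and kept contigs of at least 200 nt. It gave 43154 contigs of 20.2 Mb in all, with a mean length of 469 nt and an N50 of 547 nt. Each 25-mer belongs to 1 contig only, so near-identical gene copies, common in soybean, share a contig or compete for reads. A read was counted for the contig holding most of its 25-mers, with at least 10 and no tie. BLAST+ 2.17.0 set aside 35 ribosomal RNA contigs, leaving 43119. A near-identical copy was a match to another contig of at least 90% identity over 100 nt or more, which 2441 contigs had.

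Protein families were assigned with tblastn from 125 protein segments written from general knowledge of plant proteins, with no database, at an E-value of at most 1e-08 over at least 40 amino acids and at an identity set per family (40% for most). A family name therefore states resemblance to a segment and no gene identity. The median identity was 63.9%, 837 contigs had a family, 502 fell in a list, and the same segments reversed gave 0 matches. The names of the 23 lists were fixed before the data were examined, as were the 4-fold rule, the prior of 1 CPM, the minimum of 10 CPM, the rule for named genes and most alternatives. The segments were written after the data had been opened, and those outside the lists after the most abundant and most enriched contigs had been seen. The assembly settings were chosen after trial assemblies, and adapter masking and the removal of ribosomal RNA contigs were decided from the data. Segments for dicer-like proteins, RNA polymerases IV and V and chromatin remodellers of the methylation pathway were not used here, and a segment of RNA-dependent RNA polymerase matched no contig.

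The library totals were 4264320 reads for root, 7178888 for stem, 9149923 for leaf and 13104289 for cotyledon, in 2678906, 4706866, 5045283 and 5364271 distinct sequences. Counted reads were 2338707, 3947995, 3708849 and 9170632, so 3 reads correspond to 1.28, 0.760, 0.809 and 0.327 CPM. Levels are counted reads per 1000000 counted reads (CPM), with no correction for contig length. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Levels carry exact Poisson, shares exact Clopper-Pearson and ratios exact conditional binomial 95% intervals. A ratio to a library with 0 reads was computed against a floor of 3 reads in that library and is a lower bound.

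Libraries were grouped by organ as labelled. No test was run and no p-value is given, since 1 library per organ has no replicate spread. Organ-enriched contigs had at least 10 CPM and (CPM + 1) at least 4 times that of the highest of the other 3 organs, and contigs lower in an organ met the mirrored rule. Pairs of organs were compared by the same fold and minimum. Detection meant at least 3 reads, at full depth and after thinning to 2338707 reads. Similarity was Pearson r and Spearman rho of log2(CPM + 1). For a list, the median log2 ratio of an organ over the mean of the other 3 was taken over contigs of at least 1 CPM in any library, beside 10000 random lists of the same size drawn from 20 bins of mean expression. A list with under 5 contigs was given by contig. Counts of list members use a 2-fold difference from each other organ.

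Contigs were named by these parts of the rule: the 8 largest ratios over the highest other organ in root, stem and leaf and the 15 in cotyledon, at 50 CPM or more; the 10 lowest ratios in cotyledon among contigs of at least 50 CPM in the other 3; the 5 most abundant of each library; and for each list up to 4 contigs with the highest mean CPM, or 8 for DNA methylation. Contigs without a family keep their rank and are given as a number. A few list contigs outside this rule were named after their values were seen.

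The alternatives were median-of-ratios and trimmed-mean size factors, distinct reads counted once, thinning, priors of 0.1 and 5 CPM, minima of 1 and 50 CPM, folds of 2 and 8, other detection limits, removal of contigs with a near-identical copy, and, chosen after the data were seen, 31-mers, adapter left in, ribosomal RNA kept in the total and a family identity of at least 60%. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

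The procedure was tested on simulated data, with 4000 contigs of the same assembly used as transcripts, which is easier than real reads. They were drawn from the longer contigs with more reads, and no change near the 4-fold limit was simulated. The shares called therefore do not hold for short or low contigs or for changes near that limit. Of 50 contigs set 8-fold higher in cotyledon 100% were called, of 50 set 16-fold higher 98%, of 50 set 8-fold lower 94% and of 50 set 16-fold lower 98%. None of 3800 unchanged contigs was called (0). The simulation held counting and sequencing error but no PCR repeats and no variation between samples. The 0 calls therefore do not measure false calls between single libraries. A simulated list of 20 shifted contigs stood at percentile 100 and an unchanged one at 44.7. The shifted contigs were taken from those set 8-fold higher, so their high percentile was given by construction.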

Results

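Poly(A) RNA was sequenced from 4 organs of the soybean (Glycine max) cultivar Heinong44, with 1 library per organ: root, stem and leaf at 14 days after germination, and cotyledon at 20 days after flowering. The library totals were 4264320 reads for root, 7178888 for stem, 9149923 for leaf and 13104289 for cotyledon. After reads in ribosomal RNA were set aside, 2338707 root, 3947995 stem, 3708849 leaf and 9170632 cotyledon reads were counted in 43119 assembled transcript pieces (contigs), of which 837 could be given a protein family. A contig is named here by its family and its length in nt, and its level is given in CPM, counted reads per 1000000 counted reads. CPM is not corrected for length, so a longer contig collects more reads from the same number of messages. The most abundant contigs are those with the most reads, and their order may differ from that of message numbers. With 1 library per organ there are no replicates, so no difference below has a replicate check and no test was run. Intervals are exact 95% intervals (Poisson for a level, Clopper-Pearson for a share, conditional binomial for a ratio) and cover counting error only. Cotyledon differed from the other organs in age, growing place, read length (96 against 76 nt) and share of reads with adapter sequence as well as in organ, so these cannot be told apart.

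The first comparison asked where the reads of each organ fell. Leaf gave the largest share of ribosomal RNA, the structural RNA of the ribosome: 52.1% of its placed reads (95% interval 52.1 to 52.2%). That share was 32.7% in stem, 31.6% in root and 14.6% in cotyledon. The share of all reads that could be placed on a contig was alike in the 4 organs, at 80.2% in root, 81.7% in stem, 84.7% in leaf and 82.0% in cotyledon. Contigs with a protein family held 12.4% of the counted reads in root, 13.3% in stem, 25.1% in leaf and 33.8% in cotyledon. The floor of 3 reads, used in place of a count of 0, corresponds to 1.28 CPM in root, 0.760 in stem, 0.809 in leaf and 0.327 in cotyledon. Genome positions are not given, since no genome sequence was used here.

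**Figure D1:**
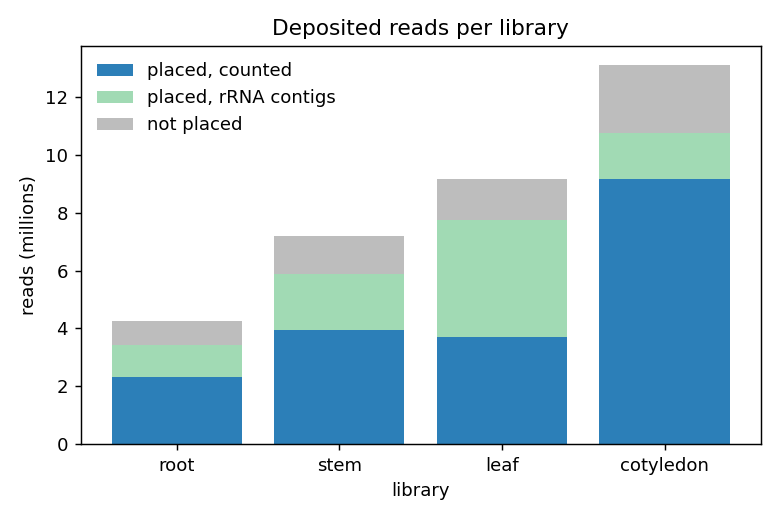
Stacked bars show the deposited reads of each library, in units of 1000000, split into reads counted on contigs, reads on ribosomal RNA contigs and reads not placed. Cotyledon had 13104289 reads in all and root 4264320, and the ribosomal part was the largest in leaf, at 4040110 reads.

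The next comparison asked which transcripts set the seed cotyledon apart from root, stem and leaf. Messages for proteins stored in the seed led the cotyledon library. The most abundant contig by CPM was beta-conglycinin 2039 nt, which encodes a vicilin-type storage globulin, at 62385 CPM (6.24% of the counted reads). It was followed by P34 thiol protease-like protein 1473 nt, a seed vacuole protein, at 45249.9 CPM, and by glycinin 1783 nt, a legumin-type storage globulin, at 24043 CPM. Kunitz trypsin inhibitor 865 nt and Bowman-Birk inhibitor 511 nt, both of which encode inhibitors of digestive proteases, stood at 23962 and 17310.4 CPM.

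In total 790 contigs were at least 4-fold higher in cotyledon than in each of the other organs, and they held 37.9% of the cotyledon reads. Against these, 343 contigs were at least 4-fold lower in cotyledon than in each of the other organs. Both counts depend on the counting and scaling: 1303 were higher with distinct reads counted once and 1036 with median-of-ratios factors, and 301 were lower with those factors and 140 with ribosomal reads kept in the total. Beta-conglycinin 2039 nt was 2978-fold higher than in root, the highest of the other 3 (2252 to 4025). P34 1473 nt was 33565-fold above leaf (14383 to 103374), where it had 5 reads. Bowman-Birk inhibitor 427 nt, glycinin 214 nt and 2S albumin 762 nt, the last a sulfur-rich storage protein, had no read in the vegetative organs and were at least 3583-fold, 1945-fold and 1397-fold higher in cotyledon, against a floor of 3 reads per library. Seed lectin 1041 nt, a sugar-binding seed protein, had 76811 reads in cotyledon and 1 in the stem library, a ratio of 33068 with an interval of 5935 to 1306110. Sucrose-binding protein 1820 nt, a vicilin relative, reached 9178 CPM, and oleosin 1016 nt, the coat protein of oil bodies, 8417 CPM. The rest of the 15 contigs with the largest ratios were Kunitz trypsin inhibitor 909 nt, glycinin 1924 nt, beta-conglycinin 400 nt and a papain-like cysteine protease of 1310 nt, between 3310 and 9309 CPM.

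The lowest cotyledon ratios belonged to single contigs of several families. GDSL esterase 476 nt, of a family that modifies surface lipids and wall polymers, had 0 reads in cotyledon and 169 to 219 CPM in the other organs, and was at least 517-fold lower. A second GDSL esterase contig, of 289 nt, was at least 318-fold lower. Fasciclin-like arabinogalactan protein 733 nt, a wall-anchored glycoprotein, had 2 cotyledon reads and was 263-fold lower than in leaf (72.0 to 2189). Lipoxygenase 592 nt, which oxidises unsaturated fatty acids, stood at 16.8 CPM in cotyledon and 738 CPM in stem, a difference of 43.9-fold (37.3 to 52.0). The lipoxygenase family as a whole was not low in cotyledon, with 11195 CPM summed over 57 contigs against 11365 CPM in root and 4773 CPM in leaf. MLP-like protein 542 nt, of the major latex protein family, and an AP2-type transcription factor of 724 nt were 94.8-fold and 86.5-fold lower than in leaf. The remaining 4 of these 10 contigs had no family.

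**Figure D2:**
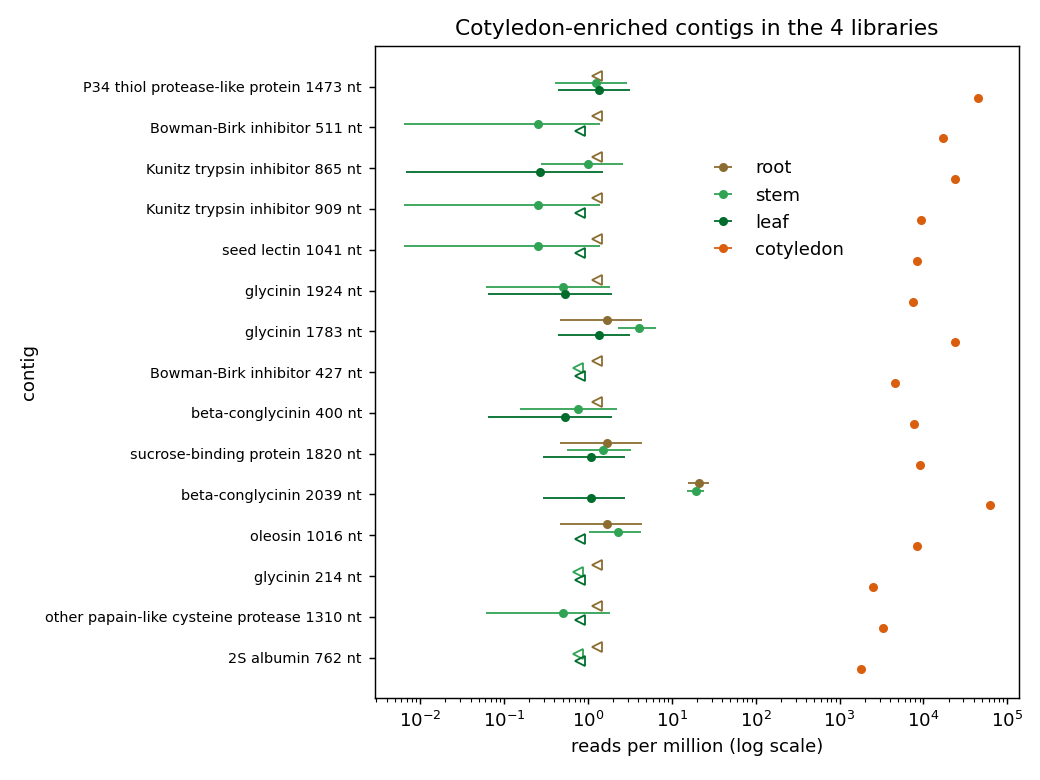
Points show the level in CPM (log axis) of the 15 contigs with the largest cotyledon ratio in each of the 4 libraries, with exact Poisson 95% intervals, and open triangles mark the level of 3 reads where a library had 0. Every cotyledon level lies between 1792 and 62385 CPM, while the highest level in another organ is 21.0 CPM.

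A further comparison asked which transcripts each vegetative organ held above all others. Root was led by copper amine oxidase 2149 nt, which oxidises polyamines, at 3484 CPM against 2.03 CPM in stem (1719-fold, 872 to 3983). Class III peroxidases, secreted enzymes that act on wall phenolics, made up 36 of the 95 root-enriched contigs with a family. Stem was led by endo-beta-mannanase 1386 nt, which cuts wall mannans, at 1384 CPM and 635-fold above cotyledon (411 to 1040.0). Leaf was led by a papain-like cysteine protease of 763 nt, at 250 CPM and at least 195-fold higher than in root.

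By the 4-fold rule 736 contigs were enriched in root, 493 in stem, 855 in leaf and 790 in cotyledon. These held 10.6% of the root reads, 6.24% of the stem reads and 40.6% of the leaf reads. The leaf and stem numbers depend on the scaling, with 1826 leaf and 327 stem contigs by median-of-ratios factors and 371 leaf contigs when ribosomal reads are kept in the total. Class III peroxidase 1035 nt stood at 737 CPM in root and was 965-fold above cotyledon, and class III peroxidase 838 nt had no read outside root and was at least 255-fold higher there. Hybrid proline-rich protein 505 nt, a wall-associated protein, stood at 717 CPM in root and 1.01 CPM in stem. In stem, a beta-glucosidase of family GH1 of 1782 nt, which releases glucose from glycosides, was the most abundant of the enriched contigs at 6362 CPM and 40.1-fold above leaf. Class III peroxidase 993 nt, BAHD acyltransferase 1131 nt, glutathione S-transferase 477 nt and 2-oxoglutarate-dependent dioxygenase 583 nt, the last 3 from families of secondary metabolism and detoxification, were between 72.3-fold and 179-fold higher in stem. Germin-like protein 743 nt, an apoplastic cupin, reached 741 CPM in leaf and 4.81 CPM in stem. Polyphenol oxidase 629 nt, a plastid oxidase of phenolics, and nitrate reductase 323 nt, the first enzyme of nitrate assimilation, stood at 184 and 72.8 CPM in leaf, the second with no read elsewhere and so at least 56.8-fold higher. Kunitz trypsin inhibitor 781 nt and subtilisin-like protease 1078 nt were 123-fold and 105-fold higher in leaf. Of the contigs with the largest ratios, 4 in root, 2 in stem and 2 in leaf had no family.

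The most abundant leaf contigs came from carbon fixation and light harvesting. Rubisco small subunit 791 nt, part of the enzyme that fixes carbon dioxide, held 79558 CPM in leaf, 9263 in stem, 772 in cotyledon and 34.6 in root. Rubisco activase 1586 nt reached 12709.6 CPM in leaf, light-harvesting chlorophyll a/b protein 1037 nt 10270.0 CPM, carbonic anhydrase 1229 nt 10113 CPM and plastid fructose-bisphosphate aldolase 1447 nt 8426 CPM. In root the abundant contigs with a family were extensin 1051 nt, a structural wall protein, at 7519 CPM, BURP domain protein 1097 nt at 5227 CPM and repetitive proline-rich protein 288 nt at 4871 CPM. The last of these was almost as high in cotyledon, at 4600 CPM. BURP domain protein 1097 nt was also among the 5 most abundant in stem, at 6191 CPM. An unnamed contig of 437 nt led both root and stem, at 11744 and 10593 CPM.

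Families of related function were compared next, to ask which processes rise or fall in each organ. Seed storage proteins had the highest cotyledon median, a log2 ratio of 8.46 over the mean of the other 3 organs, and all 15 measured contigs were at least 2-fold above each other organ. Protease inhibitors and seed lectin followed with a median of 6.45 (9 of 16 contigs higher) and oil body proteins with 4.61 (5 of 9). The oil body list split by family: the 5 oleosins were all higher in cotyledon, while the 4 caleosins, calcium-binding oil body proteins, summed to 23.3 CPM there and 186 CPM in stem. Photosynthesis marked leaf: the medians were 4.10 for the Calvin cycle, 3.33 for light harvesting and photosystems and 3.32 for genes of the plastid genome. Class III peroxidases marked root with a median of 3.24, and 41 of 69 contigs were at least 2-fold above each other organ.

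Each median is set beside 10000 random lists matched on mean expression, as a description of these libraries. The random lists draw contigs singly. Some contigs of a list may be pieces of the same transcript and move together, so percentiles near 0 or 100 may be overstated. Seed storage proteins, protease inhibitors and seed lectin, and oil body proteins stood at percentile 100 in cotyledon, as did histones, the packing proteins of DNA, with a median of 0.35. Histones stood at percentile 100 in root as well, with a larger median of 1.13, and in leaf the median was -2.10 with 20 of 36 contigs lower. The order of root and cotyledon turned with median-of-ratios factors (0.62 in root, 0.80 in cotyledon) and with trimmed-mean factors (0.65 and 0.73). The median over all contigs was 0.22 in root, 0.15 in stem, -0.73 in leaf and -0.38 in cotyledon, and median-of-ratios factors moved these to -0.18, -0.21, -0.18 and -0.09, so a list is read relative to the random lists. Fatty acid and triacylglycerol synthesis had a cotyledon median of 0.72 (percentile 99.99, random median -0.55), with 7 of 17 contigs higher there. FAD2 desaturase 1602 nt, which makes linoleic acid, stood at 1751 CPM in cotyledon and at most 0.809 CPM elsewhere, while FAD2 1263 nt was lower in cotyledon (149 CPM) than in root (371), stem (303) and leaf (375). Embryo regulators had a median of 2.20 over 7 contigs. B3 domain of ABI3 type 821 nt, a regulator of seed maturation, had 131 CPM in cotyledon and 1 read elsewhere, and an AP2 contig of WRI1 type of 1450 nt, a regulator of oil synthesis, had 106 CPM in cotyledon and 29.5 CPM in root. NF-YB 2213 nt, whose matched domain is shared by many NF-YB subunits, ranged by CPM from 251 in stem to 395 in cotyledon. Late embryogenesis proteins had only 2 measured contigs, LEA group 1 (Em) 454 nt at 141 CPM and LEA D-34 260 nt at 6.87 CPM in cotyledon, the latter with 2 reads in root. Cell cycle and ribosomal protein lists both had a cotyledon median of 0.20 (percentiles 99.3 and 99.1) and higher root medians of 1.33 and 0.89. For ribosomal proteins root was lower than cotyledon with median-of-ratios factors (0.34 against 0.54) and trimmed-mean factors (0.36 against 0.48). The cotyledon percentiles fell as low as 92.0 for the cell cycle, against the highest other organ. For ribosomal proteins they fell to 82.9, with distinct reads counted once.

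Lists with a low cotyledon median were the Calvin cycle (median -3.69), the plastid genome (-2.92), class III peroxidases (-2.83), light harvesting (-2.65), defence (-2.42), vegetative storage (-1.89), secondary wall and lignin (-1.79) and casparian strip and root transport (-1.42), all at or below percentile 2.01. For casparian strip and root transport the percentile rose to 4.56, and for the plastid genome to 2.59, with members of at least 10 CPM. The vegetative storage list was 57 lipoxygenases and 10 vegetative storage proteins, so its values are mainly those of lipoxygenases. The vegetative storage proteins alone summed to 165 CPM in cotyledon, 231 in root, 6003 in stem and 4992 in leaf. The casparian strip and root transport list was 12 tonoplast aquaporins, 11 dirigent proteins and 1 nitrate transporter, and held no other family. Members of some of these lists went both ways. In cotyledon, 18 of the 67 vegetative storage contigs were at least 2-fold higher and 15 lower than in each other organ. By the same rule 4 of the 24 casparian strip and root transport contigs were higher and 4 lower. Of the 69 class III peroxidases 6 were higher and 7 lower, and of the 66 secondary wall and lignin contigs 7 were higher and 13 lower. In summed reads, of all these lists only defence was lowest in cotyledon. There vegetative storage held 1.14% (0.976% in leaf), class III peroxidases 0.557% (0.851% in root, 0.391% in stem and 0.0602% in leaf), casparian strip and root transport 0.324% (0.101% in leaf) and secondary wall and lignin 0.296% (0.200% in leaf). Class III peroxidase 1647 nt reached 4626 CPM in cotyledon and 1495 CPM in stem, and lipoxygenase 2907 nt 5228 CPM in cotyledon and 747 CPM in root. Dirigent protein 888 nt, which guides lignan coupling, had 1193 CPM in cotyledon and no read elsewhere. Vegetative storage protein 1007 nt, a leaf and stem nitrogen store, had 3725 CPM in leaf and 35.3 CPM in cotyledon. Secondary wall and lignin genes were highest in stem (median 0.90, 30 of 66 contigs higher), where cellulose synthase A 3316 nt stood at 1640.1 CPM and phenylalanine ammonia-lyase 2220 nt, the entry enzyme to lignin, at 1343 CPM. PR-10 family 625 nt, a defence-related protein, stood at 857 CPM in root and 1.74 CPM in cotyledon, and chalcone synthase 1325 nt, the entry enzyme to flavonoids, at 1278 and 38.5 CPM. Isoflavonoid genes had a cotyledon median of -1.28 (percentile 13.5). The cotyledon medians of heat shock (-0.38), seed coat and endosperm (-0.49) and transposon-related contigs (-0.28, 5 contigs) lay between percentiles 53.7 and 77.4, and those of seed coat and endosperm and transposon-related contigs changed sign with both other scalings and that of heat shock with median-of-ratios factors. Of the seed coat and endosperm contigs, BURP domain protein 1331 nt and anthocyanidin reductase 1220 nt, an enzyme of seed coat tannins, had 3115 and 126 CPM in cotyledon, while BURP domain protein 842 nt had 2.18 CPM there and 2169 CPM in leaf. Symbiosis had 0 matching contigs.

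**Figure D3:**
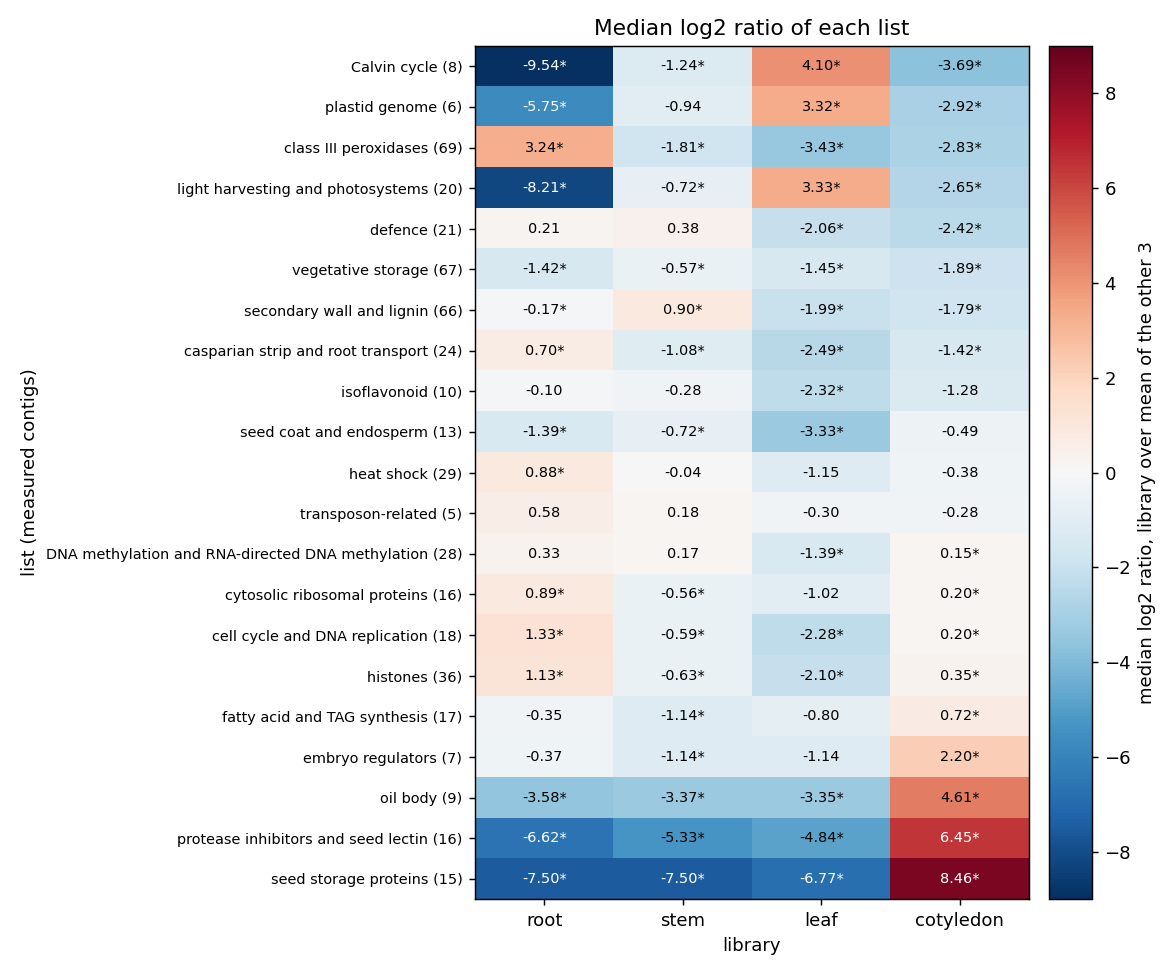
Each cell gives the median log2 ratio of a list in 1 library over the mean of the other 3, with the number of measured contigs beside the list's name, and a star marks medians in the lowest or highest 2.5% of the random lists. Cotyledon medians run from -3.69 for the Calvin cycle to 8.46 for seed storage proteins, and the sign depends on the scaling for seed coat and endosperm, heat shock and transposon-related contigs in cotyledon, for DNA methylation and defence in root and stem, and for transposon-related contigs in stem and leaf.

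The series title concerns DNA methylation, so the comparison turned to whether the genes that write, guide and erase it differ in cotyledon. Of 7 contigs of the AGO4 type, argonautes that guide small-RNA-directed methylation, 6 were higher in cotyledon than the mean of the other organs. The median log2 ratio was 0.76, the value of AGO4 242 nt. AGO4 409 nt, AGO4 363 nt and AGO4 242 nt matched the AGO4 segment at only 44.8%, 46.1% and 46.2% identity, so their type is less certain. Of these, AGO4 409 nt had a log2 ratio of -0.31 and the others were above 0. AGO4 1120 nt matched at 86.6%. The 7 contigs are 242 to 1120 nt long, so some may be pieces of the same transcript and not separate genes. AGO4 257 nt was still below stem (2.62 against 3.04 CPM). The intervals of AGO4 477 nt in cotyledon and root overlapped (28.4 and 25.7 CPM). AGO4 1120 nt stood at 75.1 CPM in cotyledon (69.6 to 81.0), 26.1 in stem, 21.0 in root and 8.09 in leaf, a log2 ratio of 1.97. AGO4 325 nt had the largest ratio of the whole list, 2.46, with 30.97 CPM in cotyledon (27.5 to 34.8) and 8.11 CPM in stem.

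Over all 28 measured contigs the median log2 ratio in cotyledon was 0.15 and 15 lay above 0, while only 2 were at least 2-fold above each other organ. That median stood at percentile 99.7 among random lists, but at 96.8 with 31-mers, 92.6 with members of at least 10 CPM and 87.6 with 60% identity. Leaf showed the clearest shift, with a median of -1.39 (percentile 0.06) and 11 contigs at least 2-fold below each other organ. The list held 0.0738% of the reads in root, 0.0753% in stem, 0.0487% in cotyledon and 0.0235% in leaf. The AGO1 type summed to 524 CPM in root, 554 in stem, 158 in leaf and 231 in cotyledon, while the AGO4 type summed to 65.8, 67.4, 25.3 and 153 CPM. The cotyledon ratio is taken over a mean that includes the low leaf values. By median-of-ratios factors the cotyledon median was 0.46, with 19 above 0. Contigs of the DRM type, which write methylation in all sequence contexts, had a median of 0.54, although the more abundant of the pair, DRM 1079 nt, stood at -0.16 and turned positive with median-of-ratios (0.26) and trimmed-mean factors (0.18). MET1 type contigs, which maintain CG methylation, had a median of -0.47, and MET1 749 nt moved from -0.39 to 0.08 and 0.01 with those factors. Chromomethylases, which write CHG and CHH methylation, had a median of -0.21, which became 0.21 and 0.15 with those factors, and the more abundant of the pair, CMT 400 nt, had 2.73 CPM in cotyledon and 10.7 CPM in root. SUVH type histone methyltransferases, which mark chromatin read by chromomethylases, had a median of 0.15 over 8 contigs. These matched their segment at 47.1 to 65.0% identity, so their type is less certain too. AGO1 type contigs, which act mainly on messenger RNA, had a median of -0.53, from AGO1 719 nt at -3.43, with 72.4 CPM in stem and 1.42 CPM in cotyledon, to AGO1 377 nt at 1.36. The most abundant contig of the list, AGO1 3151 nt, stood at 442 CPM in root and 197 CPM in cotyledon. The single contig of the DEMETER and ROS1 type, enzymes that remove methylated cytosine, had a log2 ratio of -0.74, with 3.27 CPM in cotyledon. AGO4 257 nt, AGO4 409 nt, AGO4 363 nt, AGO4 242 nt, CMT 400 nt, AGO1 377 nt and the DEMETER and ROS1 contig were singled out after their values were seen.

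**Figure D4:**
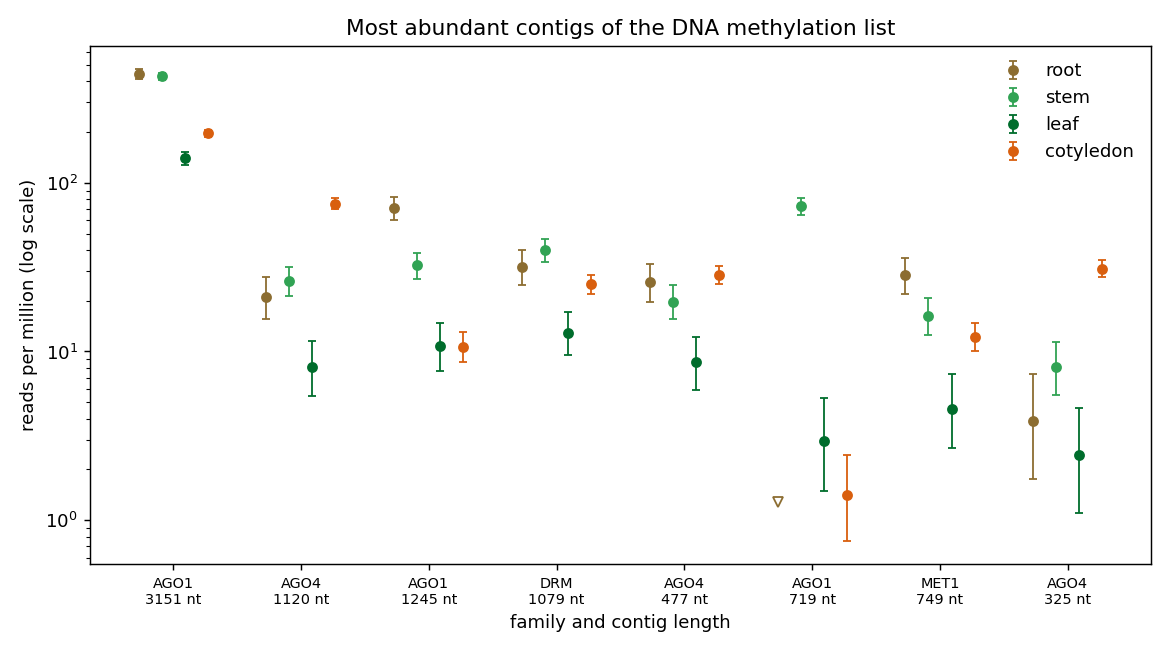
Points show the level in CPM (log axis) of the 8 most abundant contigs of the DNA methylation list in each library, with exact Poisson 95% intervals, and an open triangle marks the level of 3 reads where a library had 0. AGO4 1120 nt and AGO4 325 nt are highest in cotyledon, at 75.1 and 30.97 CPM. AGO1 3151 nt is at 442 CPM in root and 428 CPM in stem, with overlapping intervals.

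Pairs of organs were compared to ask which differed in the most transcripts. By CPM root and leaf were the farthest apart, with 5983 contigs at least 4-fold apart, and root and stem the closest, with 2827. Leaf and cotyledon were the farthest apart instead with median-of-ratios factors (5698 against 5480) and with trimmed-mean factors (5626 against 5430). At 8-fold, stem and leaf were the closest, with 1517 contigs against 1608 for root and stem. Rubisco small subunit 791 nt separated leaf from root at 79558 against 34.6 CPM, and extensin 1051 nt separated root from leaf at 7519 against 532 CPM. Leaf and cotyledon differed in 4900 contigs, 2705 of them higher in leaf.

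Between root and stem, 998 contigs were higher in root and 1829 in stem. The split between the directions depended on the scaling for 4 pairs. For root and leaf, 56.9% of the 5983 contigs were higher in root by CPM, 30.7% by median-of-ratios and 31.3% by trimmed-mean factors. For root and cotyledon, with 4626 contigs, 67.1% were higher in root by CPM, 44.6% by median-of-ratios and 46.6% by trimmed-mean factors. The stem share against leaf, over 3753 contigs, was 71.4% by CPM, 33.8% by median-of-ratios and 37.1% by trimmed-mean factors. Against cotyledon, over 4485 contigs, the stem share was 74.8%, 54.9% and 59.8% by the same scalings.

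**Figure D5:**
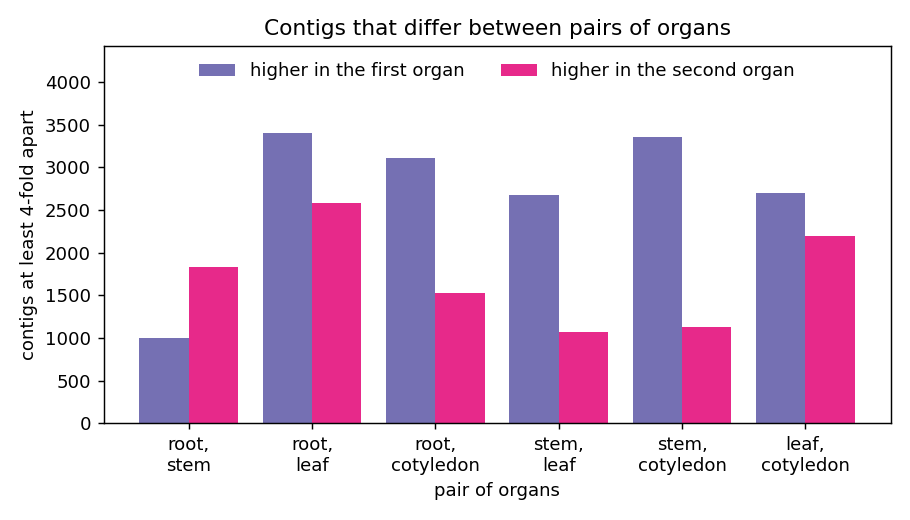
Bars show, for each of the 6 pairs, the number of contigs at least 4-fold higher in the first and in the second organ by CPM. The largest bar is 3403 contigs higher in root than in leaf, and the split between the bars changes with the scaling for root or stem against leaf or cotyledon.

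Similarity across all 43119 contigs was used to ask which organs had the closest profiles. Stem and leaf, which both hold Rubisco small subunit 791 nt among their most abundant contigs, had the highest correlation of log2 values, with a Pearson r of 0.766 and a Spearman rho of 0.732. Root and stem, which share BURP domain protein 1097 nt, had an r of 0.749 and a rho of 0.721. Cotyledon had an r of 0.599 with stem, 0.567 with root and 0.563 with leaf, and root and leaf had an r of 0.535. Which pair was lowest depends on the measure: Spearman rho was 0.502 for leaf and cotyledon, 0.513 for root and cotyledon and 0.527 for root and leaf, and with a prior of 0.1 CPM the lowest r was 0.454, for root and cotyledon. These are correlations across genes, which are not independent replicates.

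The share of reads held by a few transcripts was compared because abundant seed messages lower the CPM of all others. In cotyledon the 10 most abundant contigs, led by beta-conglycinin 2039 nt, held 21.6% of the counted reads, and in leaf, led by Rubisco small subunit 791 nt, they held 15.3%. This order turned with distinct reads counted once, to 3.35% in cotyledon and 7.16% in leaf. Counting each sequence once removes repeats by construction, which lowers contigs of many reads most. Cotyledon had 2.64 reads per distinct sequence and leaf 1.86. The turn therefore cannot tell PCR repeats from abundant messages. With all reads counted, root and stem were more even, at 5.33% and 5.17%. The 100 most abundant contigs held 37.1% in cotyledon, 35.2% in leaf, 16.9% in root and 16.1% in stem, and here leaf exceeded cotyledon with distinct reads (23.2% against 9.98%, with 10.3% in root and 10.1% in stem, so that cotyledon was then the lowest) and without near-identical copies (36.3% against 31.8%). Rubisco small subunit 791 nt alone took 7.96% of the leaf reads (95% interval 7.93 to 7.98%).

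The number of transcripts detected was compared to ask whether any organ expressed a wider set. At equal depth, 2338707 reads per library, stem had the most contigs with at least 3 reads, 38443, followed by root with 36877, cotyledon with 36130 and leaf with 32429. At full depth the numbers were 41269 in cotyledon, 40498 in stem, 36877 in root and 35571 in leaf. At equal depth 25721 contigs were detected in all 4 organs, among them NF-YB 2213 nt and AGO1 3151 nt. Contigs were assembled from the pooled reads, to which cotyledon gave the most.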

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

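The tests of scaling, carry-over and seed parts below were chosen after the results they concern had been seen, and the test of GC content before.

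Signals outside the counted transcripts were found in all 4 libraries. Ribosomal RNA contigs held 52.1% of the placed reads in leaf, 32.7% in stem, 31.6% in root and 14.6% in cotyledon, although the labels give poly(A) RNA. Adapter sequence was present in 48.0% of the leaf reads, 14.6% of the stem reads, 3.71% of the root reads and 0.0186% of the cotyledon reads. Reads on ribosomal RNA contigs were left out of the comparisons of transcripts. Adapter sequence was masked, but the rest of such a read could still be counted, and 84.7% of all leaf reads were placed. No biological explanation was tested for them.

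Cotyledon had 343 contigs at least 4-fold below root, stem and leaf, among them GDSL esterase 476 nt and lipoxygenase 592 nt. Abundant storage messages such as beta-conglycinin 2039 nt may take up reads. Were this the only cause, size factors that discount them should bring the number to under 50% of the 343. With median-of-ratios factors 301 contigs met the rule, and 238 of these were among the 343. These factors divide the CPM by 0.851 in cotyledon, 0.695 in leaf, 1.28 in stem and 1.32 in root. Cotyledon thus rose against root and stem but fell against leaf, so this number does not decide the explanation. After each library was centred within bins of GC content, 72.0% of the 343 still met the rule, which argues against GC content as the whole cause. With ribosomal reads in the total the number was 140, so the size of the group depends on the total chosen. The 790 contigs at least 4-fold higher in cotyledon held 37.9% of its counted reads. Uptake of that share of reads cannot by itself lower another contig 4-fold. This argues against uptake by abundant storage messages as the whole cause for the 343 contigs, and a partial contribution stays open. Differences of organ, age and growing place stay open and were not tested, and the read length of the cotyledon library cannot be told apart from them.

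Light-harvesting contigs had reads in cotyledon at a median of 5.83% of their leaf level (1.68 to 21.6%). Reads carried over from the leaf library would bring every abundant leaf transcript in proportion, yet carbonic anhydrase 1229 nt, the lowest of 69 other leaf-enriched contigs of at least 1000 CPM, stood at 0.00323% of its leaf level; the median of the 69 was 4.60%, near that of the light-harvesting contigs. Of the 69, 30.4% (21) had an upper limit under 50% of the light-harvesting median, where counting error alone gives at most 2.5%, which argues against carry-over as the whole cause. The bound first written asked for 50% of these contigs, which 30.4% does not reach; it was replaced by 5% after the value was seen, because carry-over allows no such contigs beyond counting error. Expression of these genes in young cotyledons stays open as an untested explanation.

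BURP domain protein 1331 nt, dirigent protein 888 nt and laccase 1931 nt, the last an oxidase of phenolics, stood at 3115, 1193 and 1067 CPM in cotyledon and at most 3.85 CPM elsewhere. RNA from the seed coat or endosperm may have come with the dissected cotyledons, and the list of seed coat and endosperm families stood at percentile 61.8 in cotyledon, at 99.99 without contigs that have a near-identical copy, which would meet the level written for this explanation, and lower than 61.8 with 31-mers and with 60% identity. These values do not decide it, since the 13 contigs go both ways and 10 of them are BURP proteins, of which BURP domain protein 1097 nt was higher in root and stem. Anthocyanidin reductase 1220 nt had 126 CPM in cotyledon, while seed coat peroxidase 373 nt had 18.8 CPM there and 27.4 CPM in root. A contribution from other seed parts cannot be told apart from expression in the cotyledon itself.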

How the results depend on the processing

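Most summary values stayed the same by the labels used, which for lists and counts do not test direction. A list was the same if its percentile stayed on the same side of the percentile limits, and a count if it stayed within 1.5 times. For these, changes of sign or split are not counted. With median-of-ratios factors the cotyledon median of seed coat and endosperm went from -0.49 to 0.08. The share higher in root than in leaf went from 56.9% to 30.7% with these factors. Of the summary values under each alternative, 431 stayed the same, 106 moved, 13 became weaker and 1 became stronger. Cotyledon lists gave 245 of the 431, and the DNA methylation list 10 more. Among the shares of the most abundant contigs 27 moved and 5 stayed the same, and among the placed shares 9 moved and 3 stayed. Among the counts of enriched contigs 21 moved and 35 stayed. Of the single contigs and of the lists in root, stem and leaf, 817 stayed the same, 17 moved, 15 became stronger, 14 became weaker and 7 reversed. Seed storage proteins, protease inhibitors and seed lectin, oil body, light harvesting, Calvin cycle and histones stayed beyond the same percentile limit in cotyledon under all alternatives run, and the numbers of detected contigs stayed within 1.5 times. For every change below, the cause was not tested unless the alternative's own construction gives it. The alternatives with 31-mers, adapter left in, ribosomal RNA in the total and 60% identity were chosen after seeing the data. Counting over whole genes with introns was not run, since the reads have no coordinates. No paired analysis was possible because each organ has 1 library and the labels pair none. At 2338707 counted reads, root sets the depth limit, with 1.28 CPM for 3 reads.

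Thresholds moved the counts by construction. With 2-fold, 1936 root, 1385 stem, 2115 leaf and 1469 cotyledon contigs were enriched and 981 were lower in cotyledon; the pairs gave 6242 (root and stem), 12391 (root and leaf), 10052 (root and cotyledon), 9592 (stem and leaf), 9494 (stem and cotyledon) and 8631 (leaf and cotyledon). With 8-fold, the same counts were 435, 173, 255 and 518, 152 lower, and 1608, 3460, 2665, 1517, 2429 and 2770 for the pairs. With a minimum of 50 CPM they were 274, 175, 508 and 360, 77 lower, and 939, 2030, 1413, 1324, 1441 and 1822. With a prior of 5 CPM they were 468, 253, 567 and 511, 156 lower, and 1646, 3424, 2523, 1959, 2421 and 2879. A minimum of 1 CPM gave 595 lower in cotyledon, against 343.

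Scaling changed the counts for leaf, for stem and for contigs lower in cotyledon. Median-of-ratios factors gave 1826 leaf and 327 stem contigs, against 855 and 493, and trimmed-mean factors gave 1740 leaf contigs. With ribosomal RNA in the total there were 371 leaf contigs and 140 lower in cotyledon. DRM 1079 nt reversed from -0.16 to 0.26 with median-of-ratios factors, 0.18 with trimmed-mean factors, 0.22 with ribosomal RNA in the total and 0.49 with distinct reads counted once. MET1 749 nt reversed from -0.39 to 0.0787, 0.00596 and 0.30 with median-of-ratios factors, trimmed-mean factors and distinct reads. Of the 790 cotyledon-enriched contigs, 769 were shared with median-of-ratios factors and 763 with trimmed-mean factors.

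Counting each distinct read once lowers contigs of many reads most, by construction. With distinct reads counted once, 1303 contigs were enriched in cotyledon, against 790, and 755 of the 790 were shared. The 10 most abundant contigs then held 2.52% in root, 2.27% in stem, 7.16% in leaf and 3.35% in cotyledon, the 100 most abundant 10.3%, 10.1%, 23.2% and 9.98%, and 73.0%, 74.9%, 75.2% and 72.0% of the distinct sequences were placed. Without contigs that have a near-identical copy, the 10 most abundant held 5.88%, 5.73%, 16.7% and 17.1% and the 100 most abundant 17.4%, 17.2%, 36.3% and 31.8%.

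The 31-mer assembly placed 76.8% of the root, 77.2% of the stem, 78.2% of the leaf and 81.1% of the cotyledon reads. Its 10 most abundant contigs held 5.88%, 5.10%, 14.3% and 21.2% and its 100 most abundant 18.03%, 15.9%, 34.6% and 39.02%. With adapter left in, 84.5% of the leaf reads were placed, the 10 and 100 most abundant leaf contigs held 14.9% and 34.7%, and the 100 most abundant stem contigs 15.9%.

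Pearson r between organs fell with a minimum of 10 CPM, to 0.614 (root and stem), 0.300 (root and leaf), 0.434 (root and cotyledon), 0.663 (stem and leaf), 0.473 (stem and cotyledon) and 0.432 (leaf and cotyledon). With a prior of 0.1 CPM it was 0.691, 0.478, 0.454, 0.494 and 0.485 for these pairs without stem and leaf. With a prior of 5 CPM it was 0.631 for root and cotyledon and 0.659 for stem and cotyledon, and with 31-mers 0.549 for stem and cotyledon.

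Among the lists, the cotyledon percentile of DNA methylation (99.7) became weaker with 31-mers (96.8), with 60% identity (87.6) and with members of at least 10 CPM (92.6). The cell cycle list fell to 97.2 with 60% identity, 92.0 against the highest other organ and 95.4 after thinning. Ribosomal proteins fell to 82.9 with distinct reads, 95.2 against the highest other organ and 94.6 without near-identical copies. The plastid genome moved to 2.59 with 31-mers and with members of at least 10 CPM, and casparian strip and root transport to 4.56 with members of at least 10 CPM and 3.10 with a prior of 5 CPM. Seed coat and endosperm became stronger without near-identical copies, at 99.99 against 61.8.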
